A study of Mus musculus with 12 samples.

How the data were processed

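The libraries measured total RNA from CCE cells, a line of mouse embryonic stem cells kept in serum medium with LIF, the cytokine that holds such cells undifferentiated. Per the labels' protocols the cells were transduced with a pLKO.1-puro lentivirus carrying a short hairpin RNA, selected with puromycin, and lysed in Trizol 2, 4 or 6 days after transduction. The hairpin targeted the long intergenic noncoding RNA TUNA (gene symbol Tunar) or was a control. The 12 libraries fall into 4 groups of 3 by their labels: control hairpin at day 2, and TUNA hairpin at day 2, day 4 and day 6. No control library of day 4 or day 6 was analysed here, so only the day 2 comparison is matched in time. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

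The authors deposited 1 table of 37477 gene symbols by 12 libraries. Its values are log2 normalized counts made by the authors, with BWA, DESeq and the mouse build mm9 named without versions or roles, per the submitters' processing notes. The deposited log2 values stop at 0, which stands for 1 normalized count or less. A row at 0 is therefore called listed at 0, and 21694 rows were at 0 in every library. The smallest steps between values gave the worth of 1 read in each library, from which totals of 3522276 to 5652838 reads per library were recovered. Between 84.0% and 92.1% of values under 20 reads lay within 0.001 of a multiple of a hundredth of a read, but only 44.3% to 57.2% lay within 0.02 of a whole read. The values are thus weighted counts, and how a read was shared between features is not given in the sources used here. No annotation of mm9 was used. A GRCm38 annotation (GENCODE M21 and RefSeq tables) served for gene names and for which genes contain which; 79.0% of the symbols matched a symbol or synonym there, and no coordinates are given.

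The plan fixed before the data were examined had been a count test, with a fallback for normalized values without whole counts. That fallback is the main test here, because the values are log2 and weighted. Values were raised back to normalized counts, with those listed at 0 set to 0, so a mean that includes them is a lower bound. Rows with at least 10 normalized counts in at least 3 libraries were kept (8739 rows). The log2 of the value plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 12 libraries, an intensity trend in the variance, 8 residual and 9.48 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05; every adjusted p of a gene below comes from this limma fit. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The 5 comparisons set each of the 3 days against the control, day 4 against day 2, and day 6 against day 4.

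For gene groups, 26 lists were fixed before the data were examined, holding 634 members, of which 628 were in the table and 381 were tested. Lists with at least 5 tested members (23 of 26) were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated from the data is given beside each call it ends. List members were counted over all genes tested and also adjusted over the list alone. The genes named were set by rule: the 10 largest rises and 10 largest falls past the threshold with a mean of at least 50 normalized counts over the 6 libraries and no overlap between groups (5 and 5 between days), the targeted RNA with genes for its reported protein partners and for pluripotency, and the 4 members of each called list with the smallest p. A few genes that this rule picks are not reported here, though they stay in every fit and count. Values are given as mean ± SD in normalized counts with n = 3, and errors of log2 changes are standard errors.

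The fit was tested on simulated counts drawn with the means, size factors and spread of the real libraries, with 200 genes changed in the day 4 group. Of 8696 simulated genes tested for day 4 against control, the fit recovered 92.2% of 4-fold, 47.8% of 2-fold and 10.8% of 1.5-fold changes, and 4.85% of its calls fell on unchanged genes. Changes of 2-fold or less are therefore often missed with 3 libraries per group. Alternatives were another scaling (median of ratios, upper quartile, trimmed mean of M values), another filter, another pseudocount, limma-voom on the recovered reads, the 2 groups alone, a stricter threshold, a block on the replicate number, the rows without snoRNA host genes, and each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.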

Results

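RNA of CCE mouse embryonic stem cells was sequenced after a hairpin against the noncoding RNA TUNA had been expressed for 2, 4 or 6 days, with a control hairpin at day 2 and 3 libraries per group. The recovered depth was 3522276 to 5652838 reads per library. Between 60.4% and 76.9% of these lay in 3 rows: Rnu3a, the U3 small nucleolar RNA, Tex14, whose gene contains annotated U3 copies, and LOC100503663. It was 73.96% to 75.52% in the controls, 72.68% to 74.48% at day 2, 64.18% to 76.9% at day 4 and 60.4% to 69.31% at day 6. Outside those rows 936460 to 2024890 reads remained, which is the depth behind the values below. Between 11925 and 13085 rows per library were listed above 0. Replicates correlated at 0.919 to 0.959 across genes. The lowest values were 0.919 for day 6 replicates 2 and 3 and 0.927 for day 4 replicates 1 and 3. Averaged over rows, the chi-square between replicates was at least 6.14 in every pair, above sampling noise. That average includes the 3 dominant rows, so it does not give the spread of a typical gene. In a principal component analysis the first component held 25.6% of the variance and ran from the control libraries (-31.32 to -23.44) through day 2 (-20.05 to -12.80) to day 6 (7.57 to 19.55) and day 4 (21.41 to 33.21).

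The targeted RNA could not be measured. Its row, under the older symbol 2810011L19Rik, was listed at 0 in all 12 libraries, so this table does not check the knockdown or the labels. Of the proteins reported to bind TUNA, Hnrnpk had 111 ± 17.8 normalized counts in the control and 122 ± 7.31, 135 ± 8.87 and 112 ± 27.0 at days 2, 4 and 6 (SD, n = 3), and passed the limma test in no comparison against the control (lowest adjusted p 0.309). Ptbp1 was lower at day 4 alone among the days, at 43.9 ± 12 against 73.2 ± 4.00 in the control (log2 change -0.76 ± 0.23, adjusted p 0.0339 by limma with Benjamini-Hochberg). That call was lost when any of 5 of the 6 libraries was left out (highest adjusted p 0.143). Ncl is described with day 2.

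The first comparison asks what the hairpin against TUNA changed at day 2, where the control is matched in time. Nop56, a core protein of box C/D small nucleolar ribonucleoproteins, and Ncl, the nucleolar protein nucleolin, were far above their control. Nucleolin is reported to bind TUNA. Nop56 had 2730 ± 1030 against 169 ± 50.4 normalized counts (SD, n = 3; 15.6-fold). Ncl had 3310 ± 492 against 487 ± 73.4 (6.79-fold). Both genes contain small nucleolar RNAs in their introns, and unstranded or intronic reads cannot be told from messenger reads here. Trim2, a ubiquitin ligase, had 125 ± 21.9 against 44.1 ± 2.91. Lpar6, a lysophosphatidic acid receptor, had 127 ± 5.90 against 57.6 ± 7.47, and Kbtbd11 145 ± 9.75 against 68.5 ± 6.98. Among called genes averaging at least 50 normalized counts over both groups without overlap, the largest falls were Sept11 and Ddx24. Sept11, a septin, stood at 52.2 ± 6.44 against 134 ± 6.72, and Ddx24, an RNA helicase, at 33.5 ± 5 against 83.5 ± 2.30. Igbp1 stood at 57.3 ± 8.25 against 138 ± 8.56 and Kpna1, an importin, at 56.5 ± 18.8 against 126 ± 10.7.

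By limma with Benjamini-Hochberg adjustment, 36 genes were higher and 48 lower at day 2 among 8739, and 1072 had an unadjusted p under 0.05. The log2 changes of the named genes were 3.96 ± 0.25 for Nop56 (adjusted p 6.73e-08), 2.76 ± 0.18 for Ncl (6.73e-08), 1.46 ± 0.20 for Trim2 (0.00162), 1.13 ± 0.16 for Lpar6 (0.00222) and 1.07 ± 0.19 for Kbtbd11 (0.00872). They were -1.35 ± 0.17 for Sept11 (0.000865) and -1.26 ± 0.17 for Igbp1 (0.00159). Fam36a (1.22), Zfp146 (1.15), Tpm1, a tropomyosin (1.13), Adc (1.1) and Cth, a cysteine synthesis enzyme (1.06), completed the rises with a mean of at least 50 normalized counts and no overlap between groups. Called genes outside that rule, such as Has2 (2.56), Rnf128 (2.49) and Wls (2.19), rose more than these. Ddx24 (-1.30), Kpna1 (-1.19), LOC100503634 (-1.18), Rbm14 (-1.11), Naa40 (-1.09), the transcription factor subunits Gtf3c4 (-1.09) and Gtf2h1 (-1.07), and Ttc4 (-1.07) completed the falls by the same rule, which leaves out Ei24 (-1.15). Of the 20 genes picked by the rule, 7 passed with each of the 6 libraries left out, and each library ended at least 1 of the other 13 calls. The counts fell to 9 to 24 higher and 9 to 21 lower with 1 library left out.

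**Figure D1:**
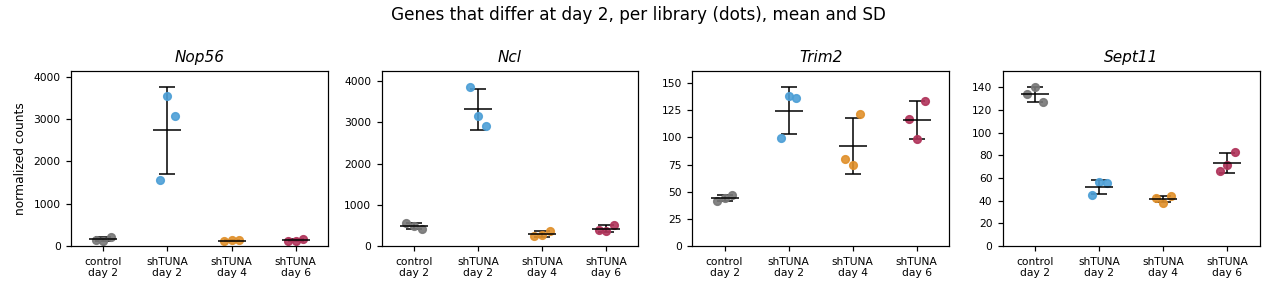
Normalized counts (vertical axes, from 0) of Nop56, Ncl, Trim2 and Sept11 by group (horizontal axes); dots are the 3 libraries of a group and bars the mean ± SD. Nop56 averages 2730 at day 2 and 130 at day 4, and Ncl 3310 and 291.

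Among the lists, p53 targets were higher at day 2: 24 of 25 tested members had a positive log2 change (median 0.25, camera adjusted p 0.000434). Single members seldom passed: over all genes Perp, a cell adhesion and apoptosis gene, was higher (1.08 ± 0.22, adjusted p 0.0292) and Ei24 lower (-1.15 ± 0.25, 0.0361). Of the list 5 were higher and 1 lower adjusted over the list alone. Plk2 (0.69 ± 0.16, 0.053) and Sesn2 (0.80 ± 0.25, 0.17) did not pass, though Plk2 did under 4 alternatives (adjusted p 0.0191 to 0.047). The calls of Perp and Ei24 were each lost with any of 5 of the 6 libraries left out (highest adjusted p 0.137 and 0.161), that of Perp with limma-voom (0.0652) and that of Ei24 without a filter (0.0586). Naive pluripotency genes had a median of -0.26 with 0 of 19 passing over all genes and 1 lower adjusted over the list alone (camera adjusted p 0.044; adjusted p = 0.307 with an estimated correlation). Its leading members Tcfcp2l1 (the older symbol of Tfcp2l1), Il6st, Pecam1 and Nr0b1 had log2 changes of -0.52 ± 0.15, 0.50 ± 0.19, -0.48 ± 0.21 and -0.43 ± 0.23. Histone genes had a median of -0.13, with 1 of 21 lower over all genes and also adjusted over the list alone, the linker histone H1f0 at -1.06 ± 0.21 (camera adjusted p 0.0378; adjusted p = 0.661 with an estimated correlation). Hist2h3b (-0.75), H2afz (-0.38) and Hist4h4 (-0.50) did not pass, and H1f0 did not with any of 4 of the libraries left out (highest adjusted p 0.127). The naive list lost its call without control replicate 1 or 2 or day 2 replicate 1 or 3 (adjusted p 0.0742 to 0.154), and the histone list without control replicate 2 or 3 or day 2 replicate 3 (0.0713 to 0.345). Of the pluripotency anchors, Nanog had 303 ± 21.4 against 482 ± 62.3 normalized counts (log2 change -0.66 ± 0.16, adjusted p 0.0702; 0.0152 with only the 2 groups), and Pou5f1 (-0.13), Sox2 (0.05) and Fgf4 (0.02) had adjusted p of 0.78 to 0.978 by limma.

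The second comparison sets TUNA hairpin cells of day 4 against the day 2 control, so hairpin and days in culture differ together. Genes of glycolysis and of the low oxygen response rose together: 15 of 26 tested members were higher and 1 lower (camera adjusted p 3.24e-13). Bnip3, a mitophagy gene induced by low oxygen, had 82.4 ± 17.1 against 9.60 ± 1.40 normalized counts (SD, n = 3; 7.79-fold). The glycolytic enzymes Tpi1 had 385 ± 46.7 against 156 ± 19.2 and Pgk1 305 ± 17.6 against 124 ± 21.7 (both 2.46-fold), and the oxygen sensor Egln3 40.2 ± 1.51 against 1.65 ± 1.46. Plod2, a collagen lysyl hydroxylase (156 ± 29.2 against 27.5 ± 6.02), Ccng2, cyclin G2 (125 ± 18.2 against 17.2 ± 0.268), and Pmaip1, the apoptosis gene Noxa (125 ± 32.0 against 27.2 ± 9.77), were the largest rises among called genes averaging at least 50 normalized counts over both groups without overlap. Mir290, a member of the main microRNA cluster of embryonic stem cells, fell to 9.71 ± 12.3 from 155 ± 22.1. Nr0b1, a nuclear receptor of naive cells, fell to 41.1 ± 7.75 from 127 ± 15.8.

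In this comparison 611 genes were higher and 678 lower of 8739 by limma with Benjamini-Hochberg adjustment. Ccng2 changed by 2.78 ± 0.23 (adjusted p 2.1e-06), Plod2 by 2.47 ± 0.20 (1.46e-06) and Pmaip1 by 2.18 ± 0.25 (3.77e-05). The integrin Itgav changed by 1.84 ± 0.16 (2.2e-06) and Skil, a regulator of TGF-beta signalling, by 1.71 ± 0.13 (1.46e-06). Ano3 (1.87), BC030307 (1.84), Flot2 (1.81), Cdk8 (1.79) and the small nucleolar RNA host Snhg11 (1.63) completed the rises. On the other side stood Mir290 (-4.49 ± 0.55, adjusted p 6.6e-05), Rps12 (-2.78 ± 0.60, 0.00505) and H2-M5 (-2.36 ± 0.21, 2.76e-06), followed by Itpk1 (-1.84), Ttc4 (-1.84), Rinl (-1.78), Ddx24 (-1.71), Sept11 (-1.67) and Nr0b1 (-1.62). Rps12, a small nucleolar RNA host as well as a ribosomal protein gene, spread from 74.14 to 1263 normalized counts among the controls. These calls held with each library left out, though the log2 change ran from -5.412 to -3.999 for Mir290 and from -3.918 to -1.882 for Rps12. The counts reached 362 higher genes without day 4 replicate 2 and 447 lower genes without control replicate 1 or 2.

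**Figure D2:**
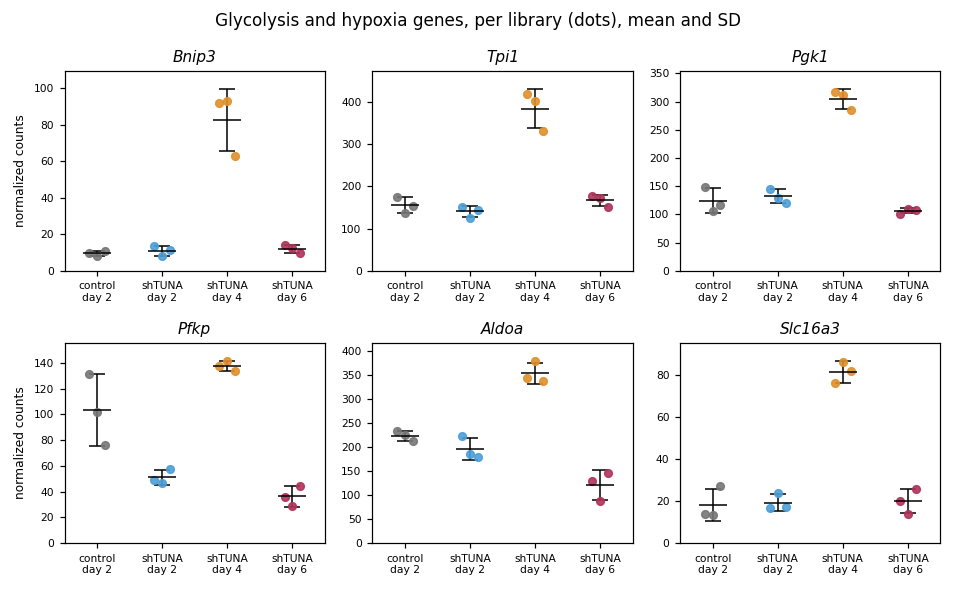
Normalized counts (vertical axes, from 0) of 6 glycolysis and hypoxia genes by group (horizontal axes); dots are the 3 libraries of a group and bars the mean ± SD. Bnip3 averages 9.60 in the control, 10.9 at day 2, 82.4 at day 4 and 12.1 at day 6.

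The glycolysis and hypoxia list had a median log2 change of 0.81, with 17 members higher and 1 lower adjusted over the list alone, and Bnip3 changed by 2.96 ± 0.28, Egln3 by 4.17 ± 0.53, Tpi1 and Pgk1 each by 1.30 ± 0.15. Its 14 enzymes of glycolysis had a median of 0.58 and the other 12 members one of 1.01. The p53 target list had 13 of 25 members higher and 1 lower (median 0.85, adjusted p 1.69e-07; 17 and 2 adjusted over the list alone), led by Ddit4 (2.41 ± 0.27), Pmaip1, Perp (1.76 ± 0.22) and the DNA polymerase Polk (1.51 ± 0.25). Ddit4 is known to respond to low oxygen as well as to p53. Both lists kept their calls with an estimated correlation (adjusted p = 0.00264 each).

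Naive pluripotency genes were lower at day 4, 7 of 19 with 1 higher (median -0.56, camera adjusted p 0.00192; adjusted p = 0.0602 with an estimated correlation; 10 lower and 2 higher adjusted over the list alone). Nr0b1, Tcfcp2l1 (-0.87 ± 0.15), Nr5a2 (-1.24 ± 0.23) and Gbx2 (-1.56 ± 0.32) led it. Pou5f1, which encodes Oct4, had 496 ± 57.1 against 737 ± 67.9 normalized counts (-0.57 ± 0.14, adjusted p 0.0113 by limma; 0.0513 at most with 1 library left out), and Ncl was now under the control at 291 ± 62.8 (-0.75 ± 0.18, 0.00959). Sox2 (0.16), Nanog (-0.23) and Fgf4 (-0.11) did not pass. S phase genes had a median of -0.225 with 6 of 31 lower (7 adjusted over the list alone; camera adjusted p 0.0184; adjusted p = 0.121 with an estimated correlation), among them Cdc6 (-1.08), Uhrf1 (-0.93), Dtl (-0.79) and Mcm3 (-0.73). Without day 4 replicate 3 the S phase list did not pass (adjusted p 0.0741), and Mcm3 lost its call without 1 of the libraries (0.0533).

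Of FGF and ERK targets, 4 of 14 were lower at day 4: Myc (-1.72 ± 0.29), Dusp6 (-0.98 ± 0.17), Etv4 (-1.85 ± 0.41) and Spry4 (-0.98 ± 0.23), with 5 lower adjusted over the list alone (median -0.35, camera adjusted p 0.0341; adjusted p = 0.319 with an estimated correlation). Histone genes were higher in 7 of 21 (9 adjusted over the list alone), such as Hist1h1b (1.00 ± 0.22), Hist1h1c (0.98 ± 0.23), Hist1h2be (0.72 ± 0.17) and H3f3b (0.70 ± 0.19), with a median of 0.56 (camera adjusted p 1.02e-05; adjusted p = 0.319 with an estimated correlation). Ribosomal protein genes had a median of 0.20, with 2 of 38 higher, Rpl30 (1.03) among them, and Rps24 (-0.73) lower, and 2 and 1 adjusted over the list alone, and Rpl23 (0.60) not passing (camera adjusted p 0.0341; adjusted p = 0.437 with an estimated correlation). The ribosomal call was lost without the host genes of small nucleolar RNAs (median 0.076, adjusted p 0.364) and without a filter (0.0668). The FGF and ERK list lost its call without control replicate 2 (adjusted p 0.0986) or day 4 replicate 1 (0.058), and the ribosomal list without control replicate 1 (0.106) or 2 (0.161) or day 4 replicate 1 (0.101). Leaving 1 library out, H3f3b (up to 0.0644) and Rps24 (0.065) lost their calls too.

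The third comparison sets day 6 against the day 2 control. Tagln, transgelin, an actin-binding protein, had 149 ± 7.43 against 6.24 ± 1.63 normalized counts (SD, n = 3), and Tpm1, a tropomyosin, 545 ± 111 against 58.2 ± 23.4 (9.55-fold). Tpm4 had 146 ± 36.5 against 28.1 ± 5.01 (5-fold) and Cnn2, calponin 2, 84.5 ± 8.12 against 19.6 ± 6.99 (4.29-fold). Acta2, smooth muscle actin, had 140 ± 37.6 at day 6, while in the control 2 libraries were listed at 0 and the mean, with these taken as 0, was at least 0.368. The keratin Krt18 (135 ± 29.1 against 17.2 ± 5.92) and Perp (116 ± 8.30 against 22.0 ± 8.22) rose as well. Nanog fell to 249 ± 44.8 from 482 ± 62.3, Fgf4 to 102 ± 6.65 from 217 ± 23.4 and Sox2 to 375 ± 15.9 from 551 ± 12.5, while Pou5f1 had 606 ± 81.9 against 737 ± 67.9 and did not pass (adjusted p 0.278).

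At day 6, 268 genes were higher and 275 lower of 8739 by limma with Benjamini-Hochberg adjustment. Tagln changed by 4.40 ± 0.37 (adjusted p 3.32e-06), Tpm1 by 3.26 ± 0.26 (3.32e-06), Krt18 by 2.93 ± 0.28 (6.43e-06) and Perp by 2.40 ± 0.22 (6.43e-06). Tpm4 changed by 2.32 ± 0.26 (3.83e-05) and Cnn2 by 2.10 ± 0.26 (9.89e-05); Acta2 passed at 1.05e-05. Lpp (1.99), Grip1 (1.93) and NEWGENE87 (1.76), a row whose identity is not given in the sources used here, completed the rises. This ranking holds among called genes averaging at least 50 normalized counts over both groups without overlap. Falls included Rps12 (-2.90 ± 0.60), H2-M5 (-2.08 ± 0.21), Nid1, the basement membrane protein nidogen (-2.00 ± 0.19, adjusted p 6.43e-06), and Ly75 (-1.92 ± 0.22). Further falls were Kdm4a, a histone demethylase (-1.55), Aebp2, a partner of Polycomb complex PRC2 (-1.49), the glycolytic enzyme Pfkp (-1.47), Ak4 (-1.45) and Rcn1 (-1.43). These calls held with each library left out, with Rps12 between -4.036 and -2.0, while the counts reached 125 higher genes without day 6 replicate 1 and 157 lower genes without control replicate 1.

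**Figure D3:**
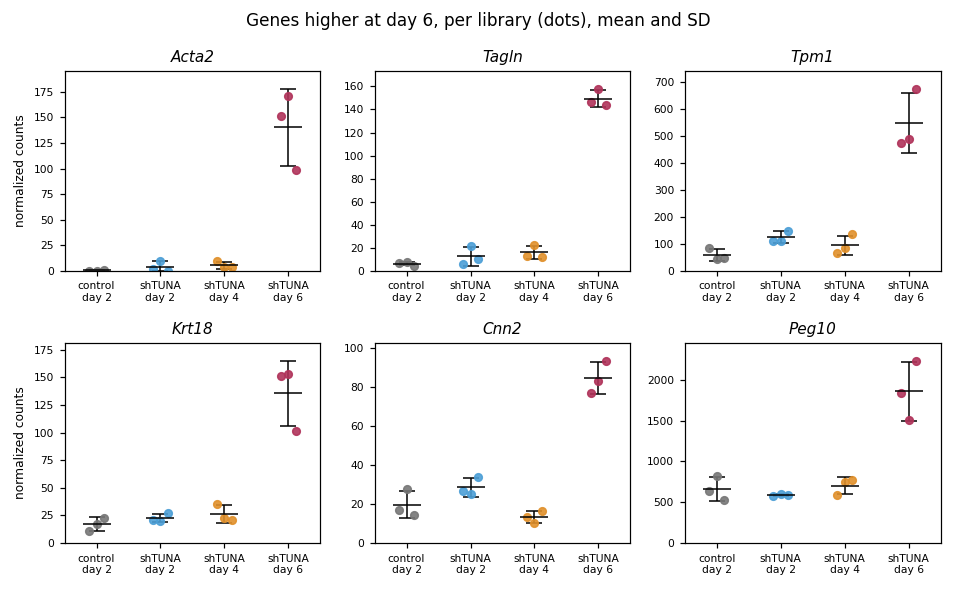
Normalized counts (vertical axes, from 0) of 6 genes called higher at day 6 by group (horizontal axes); dots are the 3 libraries of a group and bars the mean ± SD. Tagln averages 6.24 in the control, 16.0 at day 4 and 149 at day 6, and Peg10 averages 663, 702 and 1860.

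All 6 tested members of the fibroblast and feeder cell list were higher at day 6, also adjusted over the list alone (median 3.49, camera adjusted p 1.52e-10, 0.00533 with an estimated correlation). They were Tagln, Acta2, Timp3 (21.3 ± 8.88 against 2.21 ± 1.42), Thbs1 (34.7 ± 3.68 against 1.92 ± 1.71), Ctgf and Cyr61, genes of the actin cytoskeleton and secreted factors. Of the 27 members only these 6 were tested, and 5 of them pass the filter only through the day 6 libraries, which favours rises. The collagen genes of the same list, Col1a1, Col1a2 and Col3a1, and Dcn and Lum, were listed at 0 in every control and day 6 library. Extraembryonic and definitive endoderm genes were higher in 4 of 8, over all genes and adjusted over the list alone (median 0.74, adjusted p 0.00121, 0.0249 with an estimated correlation). These were the keratin Krt19 (31.3 ± 6.72 against 2.97 ± 2.58), the endocytic receptors Lrp2 (1.33 ± 0.25) and Cubn (2.09 ± 0.55) and the laminin Lamb1 (1.01 ± 0.25). With 1 library left out Lamb1 lost its call in 2 cases (up to 0.0978) and Cubn in 4 (0.107), and the change of Krt19 ran from 2.541 to 3.783. The endoderm transcripts Afp, Ttr and Apoa1 were listed at 0 in the control and at day 6.

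**Figure D4:**
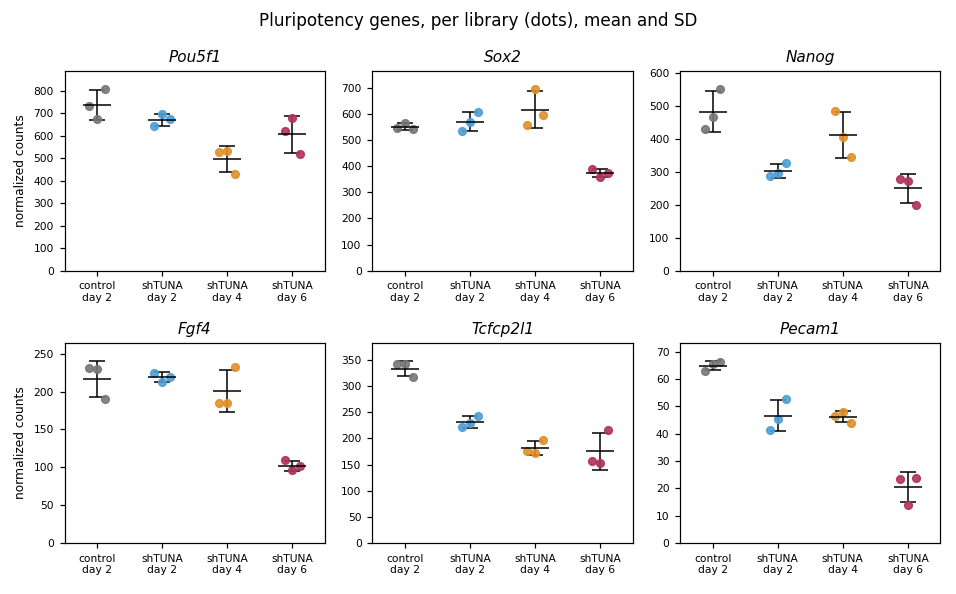
Normalized counts (vertical axes, from 0) of 6 pluripotency genes by group (horizontal axes); dots are the 3 libraries of a group and bars the mean ± SD. Fgf4 averages 217 in the control and 102 at day 6, and Pou5f1 737 and 606.

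Naive pluripotency genes were lower at day 6 in 11 of 19 with 1 higher (12 and 1 adjusted over the list alone; median -0.73, camera adjusted p 2.69e-07, 0.00533 with an estimated correlation). Pecam1 (-1.66 ± 0.21), Fgf4 (-1.07 ± 0.15, adjusted p 0.000218 by limma), Tcfcp2l1 (-0.94 ± 0.15) and Tet2, a DNA demethylase (-0.90 ± 0.16), led it. Core pluripotency genes had a median of -0.20 with 3 of 19 lower (4 adjusted over the list alone): Nanog (-0.96 ± 0.16, 0.00188), Sox2 (-0.55 ± 0.13, 0.0134) and L1td1 (-0.46 ± 0.13, 0.0469), with Tdgf1 (-0.45 ± 0.15, 0.0888) not passing. Its camera adjusted p was 0.0259 (adjusted p = 0.159 with an estimated correlation), and 0.0501 to 0.0791 without control replicate 2 or day 6 replicate 1 or 3. L1td1 lost its call with any of 5 libraries left out (up to 0.147) and Sox2 with 1 (0.055).

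Imprinted genes were higher in 7 of 15 (9 adjusted over the list alone; median 0.99, camera adjusted p 1.51e-06, 0.00533 with an estimated correlation). Peg10 had 1860 ± 359 against 663 ± 148 normalized counts (1.49 ± 0.18, adjusted p 5.33e-05 by limma), and Gnas (1.07 ± 0.22), the zinc finger gene Plagl1 (1.53 ± 0.31) and the growth factor Igf2 (2.93 ± 0.60) followed with an adjusted p of 0.00586 each. Of the 15 members 2 pass the filter only through the day 6 libraries, as does 1 of the 10 tested Nodal and BMP targets, which favours rises. The p53 targets were higher in 6 of 25 and lower in 1 (12 and 3 adjusted over the list alone; median 0.34, adjusted p 1.32e-05, 0.00533 with an estimated correlation), with Perp, Plk2 (1.04 ± 0.16), Pmaip1 (1.30 ± 0.25) and, lower, Ei24 (-1.29 ± 0.25).

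A further 3 lists passed at day 6 with the preset correlation alone. Nodal and BMP targets had 3 of 10 higher and 1 lower, over all genes and adjusted over the list alone (median 0.34, camera adjusted p 0.0435; adjusted p = 0.123 with an estimated correlation): Skil (1.13 ± 0.13), Id2 (2.38 ± 0.41) and Id3 (1.21 ± 0.25) against Nodal (-0.86 ± 0.20). S phase genes had 3 of 31 lower (5 adjusted over the list alone; median -0.23, adjusted p 0.0144; adjusted p = 0.0779 with an estimated correlation), namely Uhrf1 (-0.98), Dtl (-0.93) and Mcm4 (-0.90), with Cdc6 (-0.64) not passing. Integrated stress response genes had 2 of 19 lower and 1 higher, over all genes and adjusted over the list alone (median -0.32, adjusted p 0.0435; adjusted p = 0.15 with an estimated correlation): the amino acid enzymes Asns (-0.74) and Cth (-0.89) against Sesn2 (0.87), with Creld2 (-0.62) not passing. Without day 6 replicate 3 these lists had camera adjusted p of 0.12, 0.08 and 0.138. That library stood apart on the third principal component, at -37.63 against -8.51 and 6.68 for day 6 replicates 1 and 2. The Nodal and BMP list also failed without control replicate 2 (0.0562) or 3 (0.0542) or day 6 replicate 2 (0.0728), and the stress list without control replicate 1 (0.106) or 3 (0.0534). Sesn2 lost its call with any of the 6 libraries left out (up to 0.154), Cth in 5 (0.127), Nodal in 2 (0.0869) and Asns in 1 (0.0533). The Nodal and BMP list was also lost without a filter (0.507) and with size factors by the median of ratios (0.0665), and the stress list without a filter (0.0527).

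**Figure D5:**
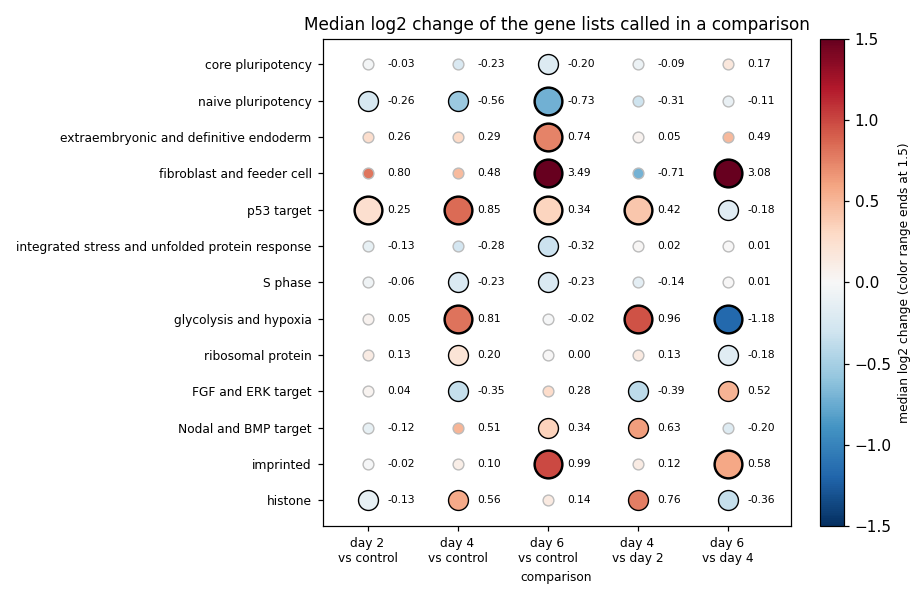
Median log2 change (number and color) of each list called in at least 1 comparison (vertical axis) by comparison (horizontal axis). Large dots with a heavy outline passed camera with both correlations, middle dots with the preset one alone and small grey-edged dots with neither; glycolysis and hypoxia reads 0.81 at day 4 and -0.02 at day 6.

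Other lists did not pass against the control at any day. At day 6 neural progenitor genes had a median of -0.04 and a mean of 0.37 over 6 tested members (camera adjusted p 0.7), formative epiblast genes -0.72 over 9 (0.38), trophoblast genes 0.39 over 7 (0.168), germ cell genes -0.41 over 6 (0.168), interferon response genes -0.30 over 6 (0.168) and Wnt targets 0.16 over 6 (0.956). Mitosis genes (-0.02, 0.996), cholesterol synthesis (-0.09, 0.456) and oxidative phosphorylation (-0.07, 0.6) stood likewise. The 5 tested genes around the TUNA locus had a median of -0.075 and a mean of -0.425 at day 6, with 1 lower (camera adjusted p 0.0898). At day 2, the comparison matched in time, all 5 were negative and 0 passed (median -0.295, camera adjusted p 0.0988, 0.316 with an estimated correlation). Mesoderm genes had 1 tested member and genes of the 2-cell-like state 2, too few for the test.

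The step from day 2 to day 4 was tested directly within the hairpin cells. Nop56 and Ncl returned from their day 2 peak, Nop56 to 130 ± 12.8 from 2730 ± 1030 normalized counts (19.8-fold lower) and Ncl to 291 ± 62.8 from 3310 ± 492 (11.5-fold lower; SD, n = 3). Ddit4 (83.6 ± 26.4 against 17.9 ± 3.72), the lactate transporter Slc16a3 (81.4 ± 5.22 against 19.2 ± 3.98), the sugar phosphate enzyme Pgm2 (83.5 ± 10.5 against 23.1 ± 5.42), Ccng2 (125 ± 18.2 against 28.5 ± 5.27) and G2e3 (481 ± 29.3 against 151 ± 4.54) were the largest rises among called genes averaging at least 50 normalized counts over both groups without overlap. Mir290 fell to 9.71 ± 12.3 from 222 ± 23.0 and Rps12 to 53.2 ± 12.9 from 1210 ± 236. By limma with Benjamini-Hochberg adjustment 286 genes were higher and 383 lower of 8739, and the adjusted p of the genes named here ran from 2.48e-09 (Ncl) to 0.000313 (Slc16a3). With 1 library left out the counts were 141 to 269 and 188 to 470, the lowest without day 4 replicate 2 and day 2 replicate 2, and the log2 change of Mir290 (-5.01) ran from -5.934 to -4.521.

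Glycolysis and hypoxia genes were higher at day 4 than at day 2 in 14 of 26 and lower in 1 (19 and 1 adjusted over the list alone; median 0.96, camera adjusted p 2.19e-15, 0.00275 with an estimated correlation), with Bnip3 at 2.81 ± 0.28, Slc16a3 at 2.04 ± 0.29, Tpi1 at 1.44 ± 0.15 and Pgk1 at 1.20 ± 0.15. The p53 targets were higher in 6 of 25 and lower in 1 (8 and 1 adjusted over the list alone; median 0.42, 0.000463, and 0.024 with an estimated correlation), with Ddit4 (2.13), Pmaip1 (1.61), Ercc5 (0.97) and Ccng1 (0.61). Histone genes were higher in 11 of 21 (17 adjusted over the list alone; median 0.76, 4.4e-12; adjusted p = 0.187 with an estimated correlation), led by H1f0 (1.51), H3f3b (1.02), Hist1h2be (0.89) and Hist1h1b (1.03). FGF and ERK targets were lower in 4 of 14 and higher in 1 (5 and 1 adjusted over the list alone; median -0.39, 0.00951; adjusted p = 0.206 with an estimated correlation), with Dusp6 (-1.44), Dusp4 (-1.46) and Myc (-1.17) against Spry1 (1.55). Nodal and BMP targets were higher in 3 of 10 (5 adjusted over the list alone; median 0.63, 0.00951; adjusted p = 0.0943 with an estimated correlation), with Skil (1.08), Id3 (1.78) and Id2 (2.59), and Id1 (1.26) not passing. With 1 library left out Ccng1 lost its call in 5 cases (up to 0.114), Myc in 3 (0.0829), and Ercc5 (0.0557) and Spry1 (0.0547) in 1 each. Myc did not pass with only the 2 groups (0.0766).

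From day 4 to day 6 the glycolysis and hypoxia list fell (camera adjusted p 4.31e-24). Pgk1 fell to 106 ± 4.91 from 305 ± 17.6 normalized counts, Aldoa to 121 ± 30.4 from 354 ± 21.9, Pfkp to 36.3 ± 7.93 from 138 ± 3.77 and Bnip3 to 12.1 ± 2.17 from 82.4 ± 17.1 (SD, n = 3). Tagln rose to 149 ± 7.43 from 16.0 ± 5.92, Tpm1 to 545 ± 111 from 95.0 ± 35.7, Krt18 to 135 ± 29.1 from 26.4 ± 8.08 and Acta2 to 140 ± 37.6 from 5.48 ± 3.58. Sox2 (-0.71 ± 0.13, adjusted p 0.00274 by limma), Nanog (-0.72 ± 0.16, 0.0145) and Fgf4 (-0.96 ± 0.15, 0.000638) were lower at day 6 than at day 4, and Ptbp1 was higher (0.87 ± 0.23, 0.0347). The call of Ptbp1 was lost with any of 4 libraries left out (up to 0.144) and that of Nanog with 2 (0.0571), and neither passed with only the 2 groups (0.118 and 0.0759). In all, 231 genes were higher and 257 lower by limma with Benjamini-Hochberg adjustment. These counts were 97 and 112 when the fit held only the 2 groups, and at lowest 99 without day 6 replicate 1 and 120 without day 4 replicate 2.

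Glycolysis and hypoxia genes were lower in 16 of 26 at day 6 against day 4, with all 26 negative (22 lower adjusted over the list alone; median -1.18, adjusted p 0.000539 with an estimated correlation). Among called genes averaging at least 50 normalized counts over both groups without overlap, the largest falls were Ccng2 (-3.31), Ddit4 (-2.23), Pgm2 (-2.04), Slc16a3 (-2.01) and Pfkp (-1.92), and NEWGENE87 (1.74) was among the rises. The fibroblast and feeder cell list had 5 of 6 higher (6 adjusted over the list alone; median 3.08, 9.3e-10, and 0.015 with an estimated correlation), with Ctgf at 24.6 ± 1.41 against 2.42 ± 1.19 and Thbs1 at 34.7 ± 3.68 against 1.19 ± 1.14. Imprinted genes had 1 of 15 higher (7 adjusted over the list alone; median 0.58, 0.000419, and 0.0261 with an estimated correlation), Peg10 at 1.40 ± 0.18, with Igf2 (2.02), Ndn (1.11) and Mest (0.76) not passing. FGF and ERK targets were higher in 5 of 14 (6 higher and 1 lower adjusted over the list alone; median 0.52, 0.000417; adjusted p = 0.163 with an estimated correlation), with Dusp6 (1.32), Spry4 (1.64), Dusp4 (1.58) and Myc (1.70). Histone genes were lower in 3 of 21 (7 adjusted over the list alone; median -0.36, 0.000196; adjusted p = 0.431 with an estimated correlation), H1f0 (-1.42), Hist1h1c (-0.84) and H3f3b (-0.68), with Hist1h2be (-0.51) not passing. The p53 targets were lower in 3 of 25 (5 lower and 1 higher adjusted over the list alone; median -0.18, 0.0455; adjusted p = 0.133 with an estimated correlation), Ddit4, Sesn1 (-1.16) and Trp53inp1 (-0.59), with Pmaip1 (-0.88, 0.0506) not passing but doing so under 8 alternatives (0.0219 to 0.0496). Of ribosomal protein genes 0 of 38 passed, over all genes or adjusted over the list alone, with Rpsa (-0.58), Rps20 (-0.42) and Rps6 (-0.31) first by p (median -0.18, 0.0491; adjusted p = 0.632 with an estimated correlation). With 1 library left out the last 3 of these lists lost their calls, histones in 2 cases (up to 0.0577), p53 targets in 4 (0.127) and ribosomal proteins in 3 (0.612, median -0.033, without day 6 replicate 3). The ribosomal call was also lost without the host genes of small nucleolar RNAs (0.293), without a filter (0.123) and with a block on the replicate number (0.0548). H3f3b lost its call with any of the 6 libraries left out (up to 0.103), Hist1h1c in 5 (0.134), Trp53inp1 in 4 (0.125) and Sesn1 in 3 (0.0776). With only the 2 groups H3f3b (0.0789), Hist1h1c (0.132) and Trp53inp1 (0.139) did not pass, nor did H3f3b with the block (0.0584) or, without a filter, H3f3b (0.0506) and Trp53inp1 (0.0501).

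The calls of the 3 days against the control overlapped in 35 genes, 16 higher and 19 lower at every day. Has2, a hyaluronan synthase (2.56, 4.26 and 4.32 at days 2, 4 and 6), Wls, a carrier for Wnt secretion (2.19, 3.65 and 3.40), and Trim2 (1.46, 1.01 and 1.37) were among the shared rises. Mcm4 (-1.03, -0.77 and -0.90), Kdm4a (-0.98, -1.41 and -1.55), Sept11 (-1.35, -1.67 and -0.86) and Ddx24 (-1.30, -1.71 and -1.04) were among the shared falls. Has2, Wls, Trim2 and Mcm4 were picked after their values were seen. With a control left out the overlap was 16, 13 or 17 genes for replicates 1, 2 and 3. Days 2 and 4 shared 24 higher and 35 lower calls, against 2.52 and 3.72 for independent lists and 17.7 and 24.4 among the top genes of simulated unchanged groups sharing the controls. Days 2 and 6 shared 20 and 22 (1.1 and 1.51 independent, 12 and 14.7 simulated), and days 4 and 6 shared 162 and 154 (18.7 and 21.3 independent, 92.1 and 101 simulated). The fold changes of days 4 and 6 correlated at 0.61 across genes, those of days 2 and 4 at 0.49 and of days 2 and 6 at 0.44, where unchanged groups gave 0.50. The covariances were 0.217, 0.132 and 0.103 against a simulated 0.05. With 3 controls no split into 2 groups of at least 2 is possible, so part of the excess may come from the shared controls.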

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

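The results in this part were picked because the change of a named gene or list differed between days by limma with Benjamini-Hochberg adjustment. Of the tests below, those on the hosted small nucleolar RNAs, on small RNA content, on 1 library left out and on other splits of the libraries were written before their results were seen. The others were chosen after the results they bear on were seen, as was the condition that leaves endoderm cells open; the test on scaling replaced one by 3 other normalizations, which moved all genes too little to decide.

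Ncl and Nop56 were higher at day 2 alone, and fell by day 4 (log2 change -3.52 and -4.31). The bound first written for reads from their small nucleolar RNAs was poorly set: the only such row above 10 normalized counts, Snora75 in Ncl, changed by 0.43, under the bound of 0.5 against that explanation, yet gained 6700 normalized counts where Ncl gained 2830. A condition on the gain was therefore added after the value was seen, and this test cannot decide. Snora75 was higher still at day 4 (32000 against 25800) while Ncl averaged 291, which speaks against Snora75 as the source for Ncl, and leaves other small RNAs and Nop56 open. The other 190 host genes changed by a median of 0.11 (quartiles -0.053 and 0.301), which was 0.106 above other genes. A large shift of small RNA content across host genes in general is therefore not supported, but a small upward shift is not excluded. That median cannot exclude a shift limited to a few hosts. Rps12, another host, also fell from day 2 to day 4 (log2 change -4.49), though it spread widely among the controls (615 ± 602 normalized counts). An effect of the hairpin at day 2 stays open beside such a shift, untested by a second hairpin.

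Glycolysis and hypoxia genes were higher at day 4 than in the control (median 0.81) and at day 2 (0.96), and lower at day 6 than at day 4 (-1.18). For day 4 against the control, 1 library does not account for it, with a lowest median of 0.766 when each of the 6 was left out; against day 2 the lowest was 0.882, and for day 6 against day 4 the weakest was -1.065. Reads shared with pseudogenes of the enzymes cannot be the whole cause, as the members that are not glycolytic enzymes had a median of 1.014 against the control. Nor does the scaling account for it, since 1 factor per library moves all genes alike. The list's median lay 0.821 above that of all other genes (camera adjusted p = 0.00264 with an estimated correlation). Those values rest on the same comparison as the list's call and add no separate evidence. With 0 control libraries of day 4, days in culture and the hairpin cannot be told apart. The density or medium of the cultures on that day could also give it and was not tested.

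Smooth muscle and actin genes picked for their rise were higher at day 6 (Acta2 4.54, Tagln 3.20, Tpm1 2.55, Tpm4 1.39, Cnn2 2.60 and Lpp 1.73 against day 4; Cnn2 was -1.06 at day 4 against day 2), with Krt18 (2.33), and the fibroblast and feeder cell list with them (median 3.08). Fibroblasts in the cultures are an unlikely source, since the highest day 6 mean of 14 fibroblast matrix genes was 3.80 (Fbn1). Endoderm cells stay open: the highest mean among 8 endoderm genes was 8.58 (Apob), yet the planned endoderm list rose at day 6 (4 of 8 higher, adjusted p = 0.0249 with an estimated correlation). The composition of the libraries differed, as Rnu3a held 30.88% to 35.8% of reads at day 6 against 38.07% to 41.13% in the controls. The 3 other scalings moved the median change of all genes by at most 0.018 against the control and -0.018 against day 4. As for glycolysis, these scalings moved all genes too little to decide whether the scaling contributed to the rises. Effects of a shift of composition are untested. With 0 control libraries of day 6, days in culture and the hairpin cannot be told apart, and either could give it.

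Other genes named against the control differed between days 2 and 4 by log2 changes of -1.24 (Fam36a), -0.68 (Zfp146), -0.67 (Lpar6), -1.70 (Cth), -0.78 (Ttc4), 2.10 (Ccng2), 1.65 (Plod2), 1.61 (Pmaip1), 1.42 (Ano3), 1.32 (BC030307), 0.90 (Itgav), 0.90 (Flot2), 1.29 (Cdk8), 1.08 (Skil), -5.01 (Mir290), -4.49 (Rps12), -2.03 (H2-M5), -1.04 (Itpk1), -1.71 (Rinl), -1.19 (Nr0b1), -0.81 (Nid1) and 1.41 (Pfkp). Between days 4 and 6 the values were 0.80 (Lpar6), -0.81 (Adc), -1.67 (Kbtbd11), 0.81 (Sept11), 0.92 (Ttc4), 0.87 (Ptbp1), -0.71 (Sox2), -0.72 (Nanog), -0.96 (Fgf4), -3.31 (Ccng2), -1.45 (Plod2), -1.33 (BC030307), -0.55 (Itgav), -1.80 (Cdk8), -0.58 (Skil), -1.27 (Snhg11), 3.47 (Mir290), 1.74 (NEWGENE87), -1.35 (Ly75), -0.55 (Aebp2), -1.92 (Pfkp) and -0.79 (Ak4). Lists differed between days 2 and 4 by a median of 0.42 (p53 targets) and, with the preset correlation alone, of -0.39 (FGF and ERK targets; adjusted p = 0.206 with an estimated correlation), 0.63 (Nodal and BMP targets; 0.0943) and 0.76 (histones; 0.187). Between days 4 and 6 the median was 0.58 for imprinted genes. With the preset correlation alone it was -0.18 (p53 targets; adjusted p = 0.133 with an estimated correlation), -0.18 (ribosomal proteins; 0.632), 0.52 (FGF and ERK targets; 0.163) and -0.36 (histones; 0.431).

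In each comparison 1 of the 10 ways to split the 6 libraries into 3 and 3, the real one, gave as many called genes: 84 at day 2, 1289 at day 4 and 543 at day 6 against the control, 669 for day 4 against day 2 and 488 for day 6 against day 4, with at most 0, 1, 0, 0 and 1 in any other split. With 10 splits no share under 0.05 can be reached.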

How the results depend on the processing

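No named gene or list that passed its test changed sign under any alternative. Values that did not pass could: Fgf4 at day 2 ran from -0.073 to 0.069 with 1 library left out, Ptbp1 at day 6 from -0.109 to 0.347, and the trophoblast list for day 6 against day 4 from -0.504 to 1.185. Of the values compared, 3672 of named genes and 1290 of lists kept their status, passing or not passing. Calls were lost in 203 and 59 and gained in 36 and 25. A value that passed in neither fit counts as kept, whatever its size or sign. The 3 other scalings moved the median change of all genes by at most 0.036. At an adjusted p under 0.01 by limma with Benjamini-Hochberg the higher and lower genes numbered 13 and 10 at day 2, 256 and 318 at day 4, 113 and 119 at day 6, 92 and 135 for day 4 against day 2, and 80 and 97 for day 6 against day 4, with an overlap of 6. Without a filter 27 genes were lower at day 2, the overlap was 23 and 10 lists passed for day 4 against day 2. With a mean of at least 50 normalized counts 351 and 417 genes passed at day 4, 125 and 182 at day 6, and 157 were higher at day 4 against day 2. With only the 2 groups compared 73 genes were lower at day 2, and 97 and 112 passed for day 6 against day 4. With an estimated correlation 1, 2, 5, 2 and 3 lists passed, against 3, 7, 9, 5 and 7.

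With 1 library left out, higher and lower genes ranged over 9 to 24 and 9 to 21 at day 2, 362 to 572 and 447 to 715 at day 4, 125 to 237 and 157 to 319 at day 6, 141 to 269 and 188 to 470 for day 4 against day 2, and 99 to 224 and 120 to 248 for day 6 against day 4. The overlap ranged over 13 to 17 and the lists over 1 to 3, 5 to 8, 5 to 8, 5 to 8 and 4 to 8. Replicate numbers showed no clear pairing of the libraries: same-number correlations ran from -0.28 to 0.33, 2 of 18 were over 0.1, and 6 of 12 libraries were closest to their own number. The highest value, 0.33, was between replicate 3 of day 4 and replicate 3 of day 6, so a partial pairing is not excluded. The DESeq2 Wald test planned as an alternative was not run, because the recovered reads are weighted and not whole counts. The trimmed mean of M values and the median of ratios were computed by own implementations.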

Other observations

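Both groups below were thought of after nucleolar and actin genes were seen among the changed genes, and their members were chosen without those already seen. Their tests were written before the result. Unlike those of the planned lists, the camera p-values of both groups are not adjusted for the number of tests. Ribosome biogenesis factors were lower at day 4 in 14 of 37 tested genes, with 34 negative and a median log2 change of -0.478 (camera p 1.58e-09, 0.000769 with an estimated correlation). Grwd1 (-1.03 ± 0.15), the polymerase subunit Polr1b (-1.20 ± 0.22), Nop16 (-1.71 ± 0.30) and Rrp1b (-1.15 ± 0.23) were among them (n = 3). From day 4 to day 6 the list rose, 9 genes passing (median 0.453, p 9.19e-09, 0.00105 with an estimated correlation), and at day 6 against the control it had a p of 0.0783. At day 2, the comparison matched in time, 26 of 37 were negative and 0 passed (median -0.121, p 0.037, 0.107 with an estimated correlation).

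Actin cytoskeleton genes outside those already named were higher at day 6 in 2 of 18 tested, Csrp1 (2.10 ± 0.39) and Actn1 (1.12 ± 0.27), with 13 positive and a median of 0.223 (camera p 0.025, 0.0446 with an estimated correlation). Against day 4 the group had 3 higher (p 0.000587, 0.00649 with an estimated correlation). Most members did not pass.

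Genes that contain small nucleolar RNAs, 192 of them tested, showed no detected difference in calls from other genes (Fisher exact test, Benjamini-Hochberg adjusted p 0.708 in all 5 comparisons). The test counted higher and lower calls together, so it could miss a shift in a single direction. Against the control the shares called were 1.04% against 0.959% at day 2, 16.1% against 14.7% at day 4 and 4.17% against 6.26% at day 6. Hosts had median log2 changes of 0.116 at day 2, 0.105 at day 4 and 0.011 at day 6. Other genes had 0.004, -0.013 and -0.011, and these differences were not tested. At day 2 only 2 hosts were called, Nop56 and Ncl, so the test says little about them.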
